A study of Mus musculus with 20 samples.

How the data were processed

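MLE12 cells, a mouse lung alveolar epithelial line immortalised with the SV40 large T antigen, were transfected with a plasmid that expressed the intracellular domain of Notch1 (NICD1) or with the empty vector, per the labels' protocols. RNA was collected 12, 24 and 48 h later, labelled with Cy3 or Cy5 and hybridised to 20 dual-colour Agilent arrays. Each array compared NICD1 RNA with empty vector RNA of the same time point. The NICD1 RNA carried Cy5 on 3 of the 6 arrays at 12 h, and Cy5 on 3 and Cy3 on 4 of the 7 arrays at 24 h and again at 48 h. Per the series design, the replicates were independent.

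The deposited table held 45220 rows and 20 columns of log2 ratios, as judged from the values: they were signed, with medians near 0, and 50 of them lay beyond what a log10 ratio of a 16-bit scanner can reach, while the largest, 11.8, exceeded what its natural log can reach. Per the submitters' processing notes, limma was used upstream; its version is not given in the sources used here. Background correction, the normalisation within arrays, the rule behind missing values and the direction of each ratio are likewise not given in the sources used here. Column medians lay between -0.0179 and 0.0195, so the arrays appeared centred, and how they were centred stays unknown. Single channel intensities were not analysed here, so signal over background could not be judged. Missing values made up 14.2% of the table, and each array had between 37041 and 40068 values. The number of arrays limits the precision.

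The direction of each ratio was settled from the values. The fixed rule was to turn arrays of one dye orientation if arrays of opposite orientation correlated below 0, and to leave all as deposited if they correlated above 0. Of the 33 pairs of arrays of the same time and opposite orientation, 8 correlated below 0 across genes and the others above 0, between -0.126 and 0.604, so neither case applied to all arrays. Each column was therefore compared with the dye pattern of the other arrays, a choice made after the data were seen. For 18 arrays the pattern matched the labelled dye under the reading NICD1 over empty vector, with correlations across genes from 0.0212 to 0.245. For 12 h replicate 3 and 48 h replicate 3 it was opposite, at -0.171 and -0.216. Nrarp, a direct Notch target, was above 0 on all 18 arrays kept and below 0 on those 2, at -1.93 and -1.58. On 12 h replicate 3 the deposited Heyl was at -0.41, but Hey1 and Notch1, which did not pass at 12 h, were above 0, at 0.44 and 0.19; on 48 h replicate 3 Hey1 (-2.74), Heyl (-1.24) and Notch1 (-0.47) were below 0. The number of decimals pointed to the same 2 arrays: all 9 columns written with more than 7 decimals carried the Cy5 pattern and all 11 others the Cy3 pattern. A dye effect fitted with those 2 arrays turned was then taken off. The 6 of the 33 pairs that included 1 of them correlated below 0 as deposited, and the other 27 above 0. Because the turned signs entered that fit, these pairs do not test the choice. Those 2 columns were multiplied by -1. A wrong dye label alone would have left Nrarp above 0 on them, so the values point to inverted ratios with correct labels, and the labelled dye was kept. The direction of all columns together rests on the known response of Nrarp and other Notch targets.

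Rows were named from the array annotation, in which 33653 rows had 1 gene symbol, 56 had several and 11511 were not listed. Rows with several symbols or none entered only a fit per row. A gene was the mean of its named rows, and a row needed values on at least 4 arrays of each time point. This left 17051 genes from 28799 rows, of which 10023 genes had 1 row and 7028 several. Rows of a gene were also fitted singly for the named genes. Positions of the probes within transcripts and a genome build are not given in the sources used here, so a gene is located by its chromosome alone.

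Log2 ratios were fitted with limma 3.58.1 in R 4.3.3. The linear model had 3 time coefficients and 1 dye term over all 20 arrays, which shared 1 residual variance per gene. Moderated two-sided tests were made of each time coefficient and of the differences between them. The p-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 was taken as a pass. Values are given as the fitted log2 ratio ± its standard error (SE), with the number of arrays (n) that had a value. Because the variance is shared over the 3 times, the SE and p-value at 48 h do not measure the spread of those arrays alone. The SD across genes was 0.705 to 0.813 on 48 h replicates 5, 6 and 7, against 0.479 to 0.641 on the 24 h arrays. The code was tested on simulated data made with known changes on the same design. Of genes simulated with an absolute log2 ratio of 1, it recovered 77.6% at 12 h, 76.1% at 24 h, 83.6% at 48 h and 62.7% for the difference between 12 and 24 h, and from 5.13% to 6.16% of the calls were false. The simulated noise was independent between arrays and, for a gene, equally wide on all of them. The real 48 h replicates 5, 6 and 7 correlated at 0.653 to 0.686, with the dye effect taken off. The simulated shares may therefore not hold for the 48 h calls.

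Gene lists were tested with camera on the moderated statistics, with its preset correlation of 0.01, and adjusted over the 31 lists within a comparison. Beside it stand the count of members past the gene test, the count adjusted over the list alone, camera with a correlation estimated from the residuals of genes measured on all arrays, and fry. The neuroendocrine list had 4 such genes, under the minimum of 5, and got no estimated correlation. The 31 lists held 477 genes, of which 428 were measured: Notch target genes, Notch pathway components, surfactant and alveolar type II genes, alveolar type I markers, club and goblet cell markers, ciliated cell markers, basal cell markers, neuroendocrine markers, epithelial junction and keratin genes, mesenchymal transition genes, TGF-beta target genes, fibroblast markers, leukocyte markers, endothelial markers, G1/S and replication genes, G2/M and mitosis genes, p53 target genes, interferon-stimulated genes, NF-kB and inflammatory genes, ER chaperone genes, ATF4 and amino acid response genes, cholesterol synthesis genes, fatty acid synthesis genes, hypoxia and glycolysis genes, NRF2 target genes, lysosome genes, Wnt target genes, ribosome biogenesis genes, heat shock genes, immediate early and ERK response genes, and epithelial ion transport genes.

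The tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, for each time, the 8 genes with the highest and the 8 with the lowest log2 ratio among those that passed with the same sign on every array of that time, and for each difference between times the 5 highest and 5 lowest that passed. It skipped predicted loci without a proper symbol. It further named up to 4 members of each list by the F test over the 3 times, and 14 Notch and surfactant genes in any case. The text describes a subset of the genes so named, picked after their values were seen, and 1 of the genes so named is not reported here.

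Replicate numbers were tested as a pairing of the arrays across times. Residuals of the fit were correlated across genes for the 19 pairs of arrays with the same number at 2 times. These correlations lay between -0.132 and 0.139, and 1 array was closest to one of its own number. The numbers were therefore not used as pairs, and the model with a replicate block is an alternative only. Alternatives fixed beforehand were a fit without the dye term, separate fits per time point, centring and scaling of arrays, leaving out the genes of lowest spread, array quality weights, robust moderation, a fit per row, a replicate block, stricter thresholds, other list tests, and leaving out each array in turn. Chosen after seeing the data were fits with the 2 turned arrays as deposited, without those 2 arrays, and without 48 h replicates 5, 6 and 7, the fixed direction rule taken literally, and the removal of a trend with gene length. The effects of all of these are given after the results.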

Results

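The effect of overexpressing NICD1, the part of the Notch1 receptor that enters the nucleus and activates transcription once the receptor is cleaved, was measured in MLE12 cells against cells given the empty vector. MLE12 is a mouse cell line with features of alveolar type II cells, the surfactant-producing cells of the lung. Log2 ratios of NICD1 over empty vector were measured for 17051 genes on 6 arrays at 12 h, 7 at 24 h and 7 at 48 h after transfection, each array from an independent replicate. A positive value means a higher level with NICD1. Rises and falls at a time are relative to the empty vector RNA of that time. Levels were not compared across times, so a ratio can change between times through either RNA. The ratios of 12 h replicate 3 and 48 h replicate 3 pointed the other way as deposited and were turned. The labels state no purpose beyond this comparison, and the changes are given by time and then between times.

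**Figure D1:**
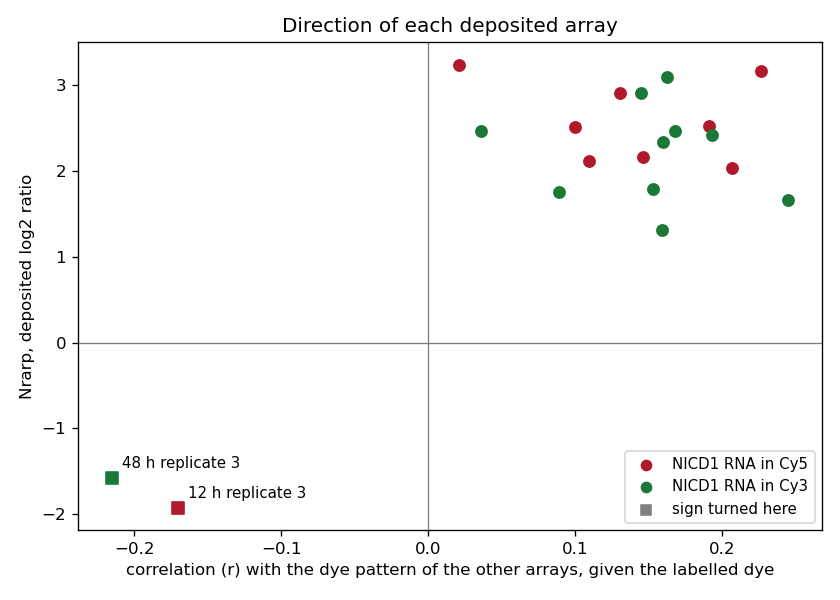
Deposited log2 ratio of Nrarp (vertical axis) against the correlation across genes (Pearson r, horizontal axis) of each array with the dye pattern of the other arrays, given the labelled dye, 1 point per array, with no error bars and colours for the dye of the NICD1 RNA. The 18 arrays kept lie between 0.0212 and 0.245, while 12 h replicate 3 and 48 h replicate 3 (squares) lie at -0.171 and -0.216.

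At 12 h, the largest rises were in Cdh15 (Entrez Gene 12555, chromosome 8), which encodes M-cadherin, and in Nrarp (67122, chromosome 2), a direct Notch target that feeds back on the pathway. Cdh15 rose by 2.40 ± 0.17 (SE, n = 6; adjusted p = 5.57e-08), a 5.28-fold change, and Nrarp by 2.08 ± 0.20 (n = 6; adjusted p = 6.68e-06), Cdh15 on all 6 arrays. The sign of Nrarp had helped to settle the direction of the arrays. The largest falls were in Hspb9, a small heat shock protein gene, at -2.73 ± 0.20, Gna15, a G protein alpha subunit gene, at -2.44 ± 0.16, and the kinase gene Sbk1 at -2.38 ± 0.14, each lower on all 6 arrays (adjusted p between 3.44e-09 and 5.57e-08). In all, 48 genes changed, 9 higher and 39 lower, and 32 of them by an absolute log2 ratio of at least 1. With the 2 turned arrays as deposited, 0 genes passed at 12 h, and without them 35 did.

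Other genes that rose at 12 h were Parp10 (1.64 ± 0.23), a mono-ADP-ribosyltransferase gene, the epidermal keratin gene Krt16 (1.27 ± 0.14), the potassium channel gene Kcng4 (1.19 ± 0.20, n = 5), the Notch target Hes1 (1.13 ± 0.19; adjusted p = 0.00628), Ntn4 (1.02 ± 0.14), which encodes netrin 4, and Pkp1 (0.94 ± 0.16), which encodes the desmosomal protein plakophilin 1. Further falls were in Zscan10 (-2.37 ± 0.13), a zinc finger gene, the kallikrein gene Klk4 (-2.00 ± 0.14), the immunoglobulin gene segment Igkv4-72 (-2.04 ± 0.14) and Nr1h4 (-1.50 ± 0.17), which encodes the bile acid receptor FXR. Chst5 fell to -2.05 ± 0.36 with n = 4, and its adjusted p of 0.0297 passed the threshold in some and not other fits that left out 1 array. Each of these lower genes was read by 1 row of the table. Among genes with several rows, 11 had a row lower at 12 h with a median of -1.52, and the 14 other rows of those genes had a median of 0.05, with none lower.

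Ifnb1, which encodes interferon beta, stood at -2.35 ± 0.32 at 12 h (n = 6; adjusted p = 0.000462), lower on all 6 arrays, with 1 array at -5.02 and the others between -2.29 and -1.38. Lyz2, a lysozyme gene expressed in alveolar type II cells and macrophages, fell to -1.45 ± 0.26, with 1 array at -2.94 and the others between -1.38 and -0.88. Adm, which encodes adrenomedullin, fell to -0.94 ± 0.18 (adjusted p = 0.019). With 12 h fitted alone 18 genes passed, 16 of them shared. Those included Cdh15, Nrarp, Krt16, Hspb9, Gna15, Sbk1, Zscan10, Klk4, Igkv4-72 and Nr1h4, but not Hes1 (adjusted p = 0.232), Pkp1, Ntn4, Parp10, Kcng4, Ifnb1 (0.225), Chst5, Lyz2 or Adm.

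Of 12 measured Notch target genes, 2 rose at 12 h, Nrarp and Hes1, none fell and 10 did not pass; adjusted over the list alone 4 rose. Their median was 0.14 and the list was shifted up (camera adjusted p = 6.31e-06; adjusted p = 0.014 with an estimated correlation). Without the 2 turned arrays its adjusted p was 0.000596, and with them as deposited 0.885. The direction of all columns together rests on Nrarp and other Notch targets. The upward sign of this list, at any of the times, is therefore not an independent result. Hey1 stood at 0.30 ± 0.19 and Heyl at 0.78 ± 0.28, and neither passed. The G1/S and replication list was shifted down with a median of -0.13 (camera adjusted p = 0.000937, and 0.0809 with an estimated correlation). None of its 19 members passed, over all genes or adjusted over the list alone. Without the 2 turned arrays only 1 list passed at 12 h, the Notch targets, so the G1/S call was lost. Mcm3 and Mcm6, which encode subunits of the replicative helicase, had -0.21 ± 0.09 and -0.13 ± 0.19, and Cdt1, which licenses replication origins, had -0.28 ± 0.24. None of the 24 interferon-stimulated genes passed at 12 h and their median was -0.05 (adjusted p = 0.682).

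**Figure D2:**
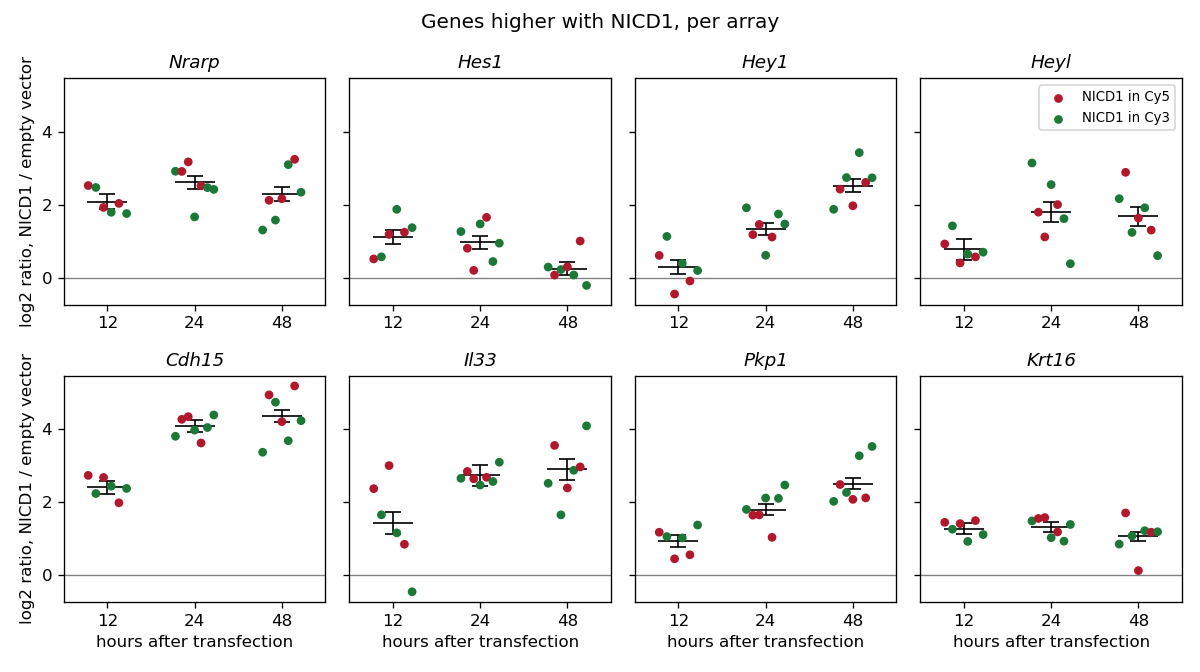
Log2 ratio of NICD1 over empty vector (vertical axis) at 12, 24 and 48 h (horizontal axis) for Nrarp, Hes1, Hey1, Heyl, Cdh15, Il33, Pkp1 and Krt16, with 1 point per array coloured by the dye of the NICD1 RNA and black bars for the fitted value ± SE. Cdh15 goes from 2.40 at 12 h to 4.35 at 48 h and Hey1 from 0.30 to 2.51, while Hes1 goes from 1.13 to 0.25.

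At 24 h, interferon-stimulated genes were lower as a group and Notch targets higher. All 24 measured interferon-stimulated genes fell, with a median of -1.79, and all 24 also when adjusted over the list alone (camera adjusted p = 4.03e-117; adjusted p = 5.80e-09 with an estimated correlation). The list's median lay between -2.10 and -1.60 on the 7 arrays. Mx2, an interferon-induced antiviral GTPase gene, fell to -3.63 ± 0.16 (n = 7; adjusted p = 1.32e-11), a 12.4-fold change, Ifit1 to -2.90 ± 0.13, Ifit3 to -2.42 ± 0.12 and Xaf1 to -2.07 ± 0.11. Cdh15 rose by 4.08 ± 0.16 (n = 7; adjusted p = 4.30e-12), a 16.9-fold change.

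Of the 17051 genes, 284 changed at 24 h, 63 higher and 221 lower, and 125 of them by an absolute log2 ratio of at least 1. Beside Mx2 and Ifit1, the lowest were Ifnb1 (-3.44 ± 0.30; adjusted p = 1.53e-07), the interferon-inducible GTPase genes Iigp1 (-3.31 ± 0.20), Gbp3 (-2.64 ± 0.13) and Igtp (-2.57 ± 0.12), the tripartite motif gene Trim30a (-2.74 ± 0.11) and Ifit3b (-3.22 ± 0.26), which was at -4.38 on 1 array and between -3.28 and -2.72 on the others. Oasl2, of the oligoadenylate synthetase family, fell to -2.38 ± 0.14, Irf7, a transcription factor of the interferon response, to -2.12 ± 0.24, Trim30d to -2.14 ± 0.20 and Ifi27l2a to -1.25 ± 0.21. Il6, which encodes interleukin 6, fell to -1.53 ± 0.14 (adjusted p = 2.83e-07). Every one of these genes was lower on all 7 arrays. Hspb9, Gna15, Sbk1, Zscan10, Igkv4-72 and Klk4 were still lower at 24 h, between -1.74 and -1.02.

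**Figure D3:**
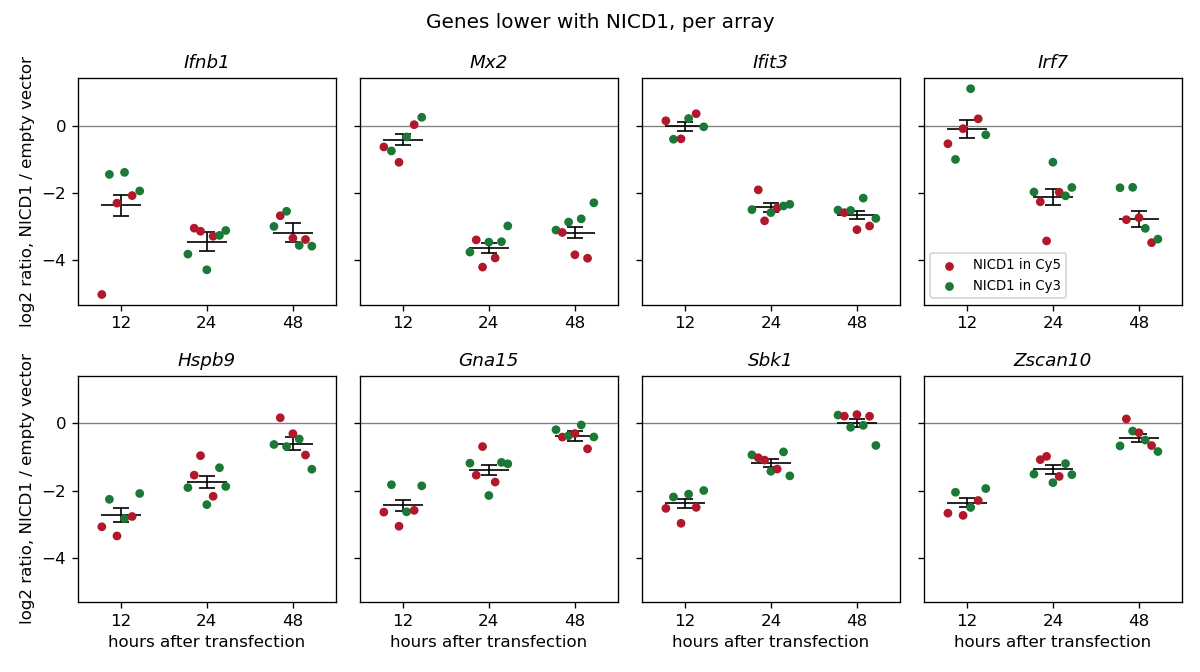
Log2 ratio of NICD1 over empty vector (vertical axis) at 12, 24 and 48 h (horizontal axis) for Ifnb1, Mx2, Ifit3, Irf7, Hspb9, Gna15, Sbk1 and Zscan10, with 1 point per array coloured by the dye of the NICD1 RNA and black bars for the fitted value ± SE. Mx2, Ifit3 and Irf7 lie near 0 at 12 h and between -3.63 and -2.12 at 24 and 48 h, whereas Hspb9, Gna15, Sbk1 and Zscan10 are lowest at 12 h.

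Genes that rose at 24 h beside Cdh15 were Il33, which encodes the alarmin interleukin 33 (2.73 ± 0.29; adjusted p = 2.49e-06), Nrarp (2.61 ± 0.19), Nts, which encodes neurotensin (1.99 ± 0.34), Oacyl (1.94 ± 0.19), which belongs to an acyltransferase family, and Pkp1 (1.79 ± 0.15). Krt16 rose by 1.31 ± 0.13, Col6a1, a collagen VI chain gene, by 1.58 ± 0.29, Ntn4 by 0.91 ± 0.13, Perp, a desmosome gene and p53 target, by 0.85 ± 0.09, and Akr1c14, of the aldo-keto reductase family, by 0.67 ± 0.11. The odorant receptor gene Olfr1184 (0.95 ± 0.21; adjusted p = 0.0187) and Aldh1b1 (0.74 ± 0.18; adjusted p = 0.0401), a mitochondrial aldehyde dehydrogenase gene, passed too, but each lost its call when any of several single arrays was left out.

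Of the 12 Notch target genes, 5 rose at 24 h and none fell, as they did adjusted over the list alone, with a median of 0.47 (camera adjusted p = 2.05e-09; adjusted p = 0.00152 with an estimated correlation). They included Nrarp, Heyl (1.80 ± 0.26), Hey1 (1.33 ± 0.17) and Hes1 (0.97 ± 0.18), all higher on 7 of 7 arrays. Fitted alone, 2 of the 12 rose, and Hes1 (adjusted p = 0.0813) and Heyl (0.0533) did not pass. Among 21 Notch pathway components 1 rose and 1 fell (list adjusted p = 0.68); adjusted over the list alone these were 1 and 2. Notch1 stood at 0.60 ± 0.14 (adjusted p = 0.0217), a call lost without any one of 5 single arrays, and the ligand gene Dll1 fell to -0.92 ± 0.10 (adjusted p = 8.39e-06). Whether the 11 rows of Notch1 lay inside the expressed domain was not known, so its value mixes the plasmid and the cell's own gene to an unknown extent.

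Small shifts of 4 further lists passed camera at 24 h, and none held with an estimated correlation. Immediate early and ERK response genes were shifted up (median 0.05, adjusted p = 0.0228; adjusted p = 0.302 with an estimated correlation): 2 of 17 rose, over all genes and adjusted over the list alone, namely the AP-1 subunit genes Fosb (0.94 ± 0.14) and Fos (0.72 ± 0.12). Cholesterol synthesis genes had a median of 0.11 with 18 of 19 members positive and none passed (adjusted p = 0.0147; adjusted p = 0.302 with an estimated correlation). Fatty acid synthesis genes had a median of 0.12 (adjusted p = 0.0147; adjusted p = 0.17 with an estimated correlation), with none of 15 passed over all genes and 1 adjusted over the list alone. ATF4 and amino acid response genes had a median of -0.11, with 0 of 17 members positive and none passed (adjusted p = 0.0194; adjusted p = 0.302 with an estimated correlation). Of 9 basal cell markers, Krt17 (0.46 ± 0.10) and Itga6 (0.42 ± 0.10) passed, and the list did not (adjusted p = 0.0842). Fitted alone, Fos (adjusted p = 0.0857), Krt17 (0.121) and Itga6 (0.104) did not pass at 24 h.

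At 48 h, Cdh15 stood at 4.35 ± 0.16 (n = 7; adjusted p = 1.32e-12), a 20.4-fold change, Il33 at 2.89 ± 0.29 and Nrarp at 2.29 ± 0.19, while Mx2 stood at -3.17 ± 0.16 (adjusted p = 1.08e-10), a 9.02-fold fall. All 24 interferon-stimulated genes were still lower, with a median of -1.68, also adjusted over the list alone (camera adjusted p = 1.69e-32; adjusted p = 9.68e-05 with an estimated correlation). Hey1 had risen by 2.51 ± 0.17 (adjusted p = 9.21e-09), and Pkp1 by 2.49 ± 0.15, higher on all 7 arrays.

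In all, 4747 genes passed at 48 h, 2392 higher and 2355 lower, of which 263 had an absolute log2 ratio of at least 1. This count rested on how the arrays were combined. Correlations across genes were taken with the fitted dye effect taken off. Replicates 5, 6 and 7 correlated with each other at 0.653 to 0.686, against 0.102 to 0.322 among replicates 1 to 4 and 0.0505 to 0.399 between those sets. Replicate 4 was the closest to them, at 0.368, 0.399 and 0.341. Without these 3 arrays 630 genes passed, 258 higher and 372 lower, 567 of them shared, and with 48 h fitted alone 234 passed, 67 higher and 167 lower, 231 of them shared. Because of this, a gene is described for 48 h with its call in those fits where it was lost, apart from the genes named under other observations.

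**Figure D4:**
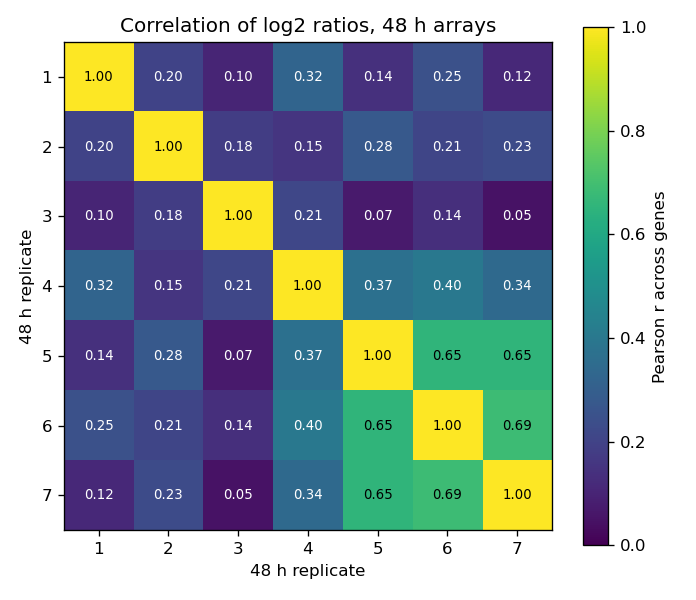
Pearson correlation across genes of the log2 ratios, with the fitted dye effect taken off, of each pair of the 7 arrays at 48 h (replicate number on both axes, colour and printed value for r, no error bars). Replicates 5, 6 and 7 correlate with each other at 0.653 to 0.686, and pairs among replicates 1 to 4 reach at most 0.322.

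The lowest genes at 48 h were Ifit3b (-3.66 ± 0.26; adjusted p = 4.83e-08), Ifnb1 (-3.17 ± 0.30), Trim30a (-3.06 ± 0.11), Iigp1 (-2.97 ± 0.20), Trim30d (-2.81 ± 0.20), Irf7 (-2.76 ± 0.24) and Ifi27l2a (-2.67 ± 0.21). Ifit3 stood at -2.65 ± 0.12, Gbp3 at -2.29 ± 0.13, Ifit1 at -2.06 ± 0.13, Xaf1 at -1.87 ± 0.11, Igtp at -1.66 ± 0.12, Il6 at -1.61 ± 0.14 and Oasl2 at -1.02 ± 0.14. Among the highest were also Col6a1 (2.86 ± 0.29, with 1 array at 4.67 and the others between 2.10 and 3.20), Nts (2.81 ± 0.34, with 1 array at 5.23 and the others between 1.77 and 3.17) and Glod5 (1.92 ± 0.25), on chromosome X. Krt16 stood at 1.06 ± 0.13 and Oacyl at 1.07 ± 0.19. All of these genes passed in the 48 h arrays fitted alone and without replicates 5, 6 and 7. With 48 h fitted alone, 20 of the 24 interferon-stimulated genes were lower. Hspb9 (-0.60 ± 0.18), Igkv4-72 (-0.52 ± 0.13) and Zscan10 (-0.43 ± 0.12) were still lower at 48 h and Ntn4 higher (0.45 ± 0.13), and none of these 4 passed fitted alone or without replicates 5, 6 and 7.

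Of the 12 Notch target genes, 7 rose at 48 h and none fell, and 8 rose adjusted over the list alone, with a median of 0.60 (camera adjusted p = 4.60e-05; adjusted p = 0.0284 with an estimated correlation). Beside Hey1 and Nrarp these included Heyl (1.68 ± 0.26) and Notch3 (0.89 ± 0.14; adjusted p = 0.00028), a receptor gene that Notch signalling itself induces. Fitted alone, 5 rose. Hes1 stood at 0.25 ± 0.18 and did not pass (adjusted p = 0.331), with 1 array at 1.01 and the others between -0.21 and 0.30. Of 21 Notch pathway components, 7 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.30, adjusted p = 0.00357; adjusted p = 0.198 with an estimated correlation). Without replicates 5, 6 and 7, 3 rose and none fell, and the list had an adjusted p of 0.0607. Notch1 stood at 1.07 ± 0.14 and the ligand gene Jag2 at 1.13 ± 0.18, while Dll1 fell to -0.31 ± 0.10 (adjusted p = 0.0356); fitted alone, Notch1 passed (adjusted p = 0.0304) and Jag2 (0.0768) and Dll1 (0.141) did not, and Dll1 did not pass without replicates 5, 6 and 7 either (0.071).

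Immediate early and ERK response genes were shifted up at 48 h with a median of 0.52 (adjusted p = 0.000628; adjusted p = 0.143 with an estimated correlation). Of 17 measured, 11 rose and none fell. Adjusted over the list alone 11 rose and 1 fell, and without replicates 5, 6 and 7 3 rose. Fos rose by 1.03 ± 0.12, Egr1, a zinc finger transcription factor gene, by 1.11 ± 0.17, Fosb by 0.71 ± 0.14 and Dusp6, which encodes an ERK phosphatase, by 0.65 ± 0.15 (adjusted p = 0.356 without replicates 5, 6 and 7). Fitted alone, Fos passed (adjusted p = 0.00763) and Egr1, Fosb and Dusp6 did not. The list's medians were 0.73, 0.83 and 0.69 on replicates 5, 6 and 7, and between 0.13 and 0.43 on the others.

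Fatty acid synthesis genes were shifted up with a median of 0.23 (adjusted p = 0.00163; adjusted p = 0.129 with an estimated correlation), 5 of 15 rose and none fell, and 6 rose adjusted over the list alone. Without replicates 5, 6 and 7, 4 rose. The desaturase gene Scd2 rose by 1.09 ± 0.15, the elongase gene Elovl6 by 0.62 ± 0.09, Fasn, the fatty acid synthase gene, by 1.04 ± 0.17 and the desaturase gene Fads2 by 0.50 ± 0.08. Fitted alone, Scd2 (adjusted p = 0.0119) and Elovl6 (0.0408) passed and Fasn (0.0847) and Fads2 (0.0864) did not. Cholesterol synthesis genes were not shifted (adjusted p = 0.463), with 5 of 19 higher and 1 lower, over all genes and adjusted over the list alone, and none of them passed fitted alone or without replicates 5, 6 and 7.

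G2/M and mitosis genes were shifted up with a median of 0.24 (adjusted p = 0.00171; adjusted p = 0.143 with an estimated correlation). Of 21 measured, 8 rose and none fell, 9 adjusted over the list alone, and 3 without replicates 5, 6 and 7. The proliferation marker gene Mki67 rose by 1.10 ± 0.15, Foxm1, a transcription factor of the G2/M programme, by 0.90 ± 0.15 and the kinetochore motor gene Cenpe by 0.72 ± 0.11. Fitted alone, Mki67 passed (adjusted p = 0.0488) and Foxm1 (0.0846) and Cenpe (0.0684) did not. Of 19 G1/S and replication genes, 6 rose and 5 fell, 7 and 5 adjusted over the list alone (list adjusted p = 0.593). Mcm3 (0.39 ± 0.09), Mcm6 (0.79 ± 0.18) and Cdt1 (1.02 ± 0.22) were higher and the thymidylate synthase gene Tyms was lower (-0.41 ± 0.10). None of these 4 passed when fitted alone or without replicates 5, 6 and 7, and no member of the list passed in either fit.

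Wnt target genes were shifted up with a median of 0.51 (adjusted p = 0.018; adjusted p = 0.129 with an estimated correlation), with 4 of 9 higher, 7 adjusted over the list alone and none lower. The 4 were Znrf3 (0.77 ± 0.18), Apcdd1 (0.53 ± 0.15), Axin2 (0.91 ± 0.31) and the stem cell marker gene Lgr5 (0.51 ± 0.17). None of them passed when fitted alone or without replicates 5, 6 and 7, and the list's adjusted p without those arrays was 0.123. Basal cell markers were shifted up with a median of 0.41 (adjusted p = 0.0249; adjusted p = 0.176 with an estimated correlation), with 5 of 9 higher and 1 lower, over all genes and adjusted over the list alone. Itgb4 (0.88 ± 0.15) and Itga6 (0.58 ± 0.10), the subunit genes of the hemidesmosome integrin, the keratin gene Krt17 (0.59 ± 0.10) and the nerve growth factor receptor gene Ngfr (0.41 ± 0.07) rose. Without replicates 5, 6 and 7 these 4 passed and the list did not (adjusted p = 0.0607), and fitted alone none passed.

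**Figure D5:**
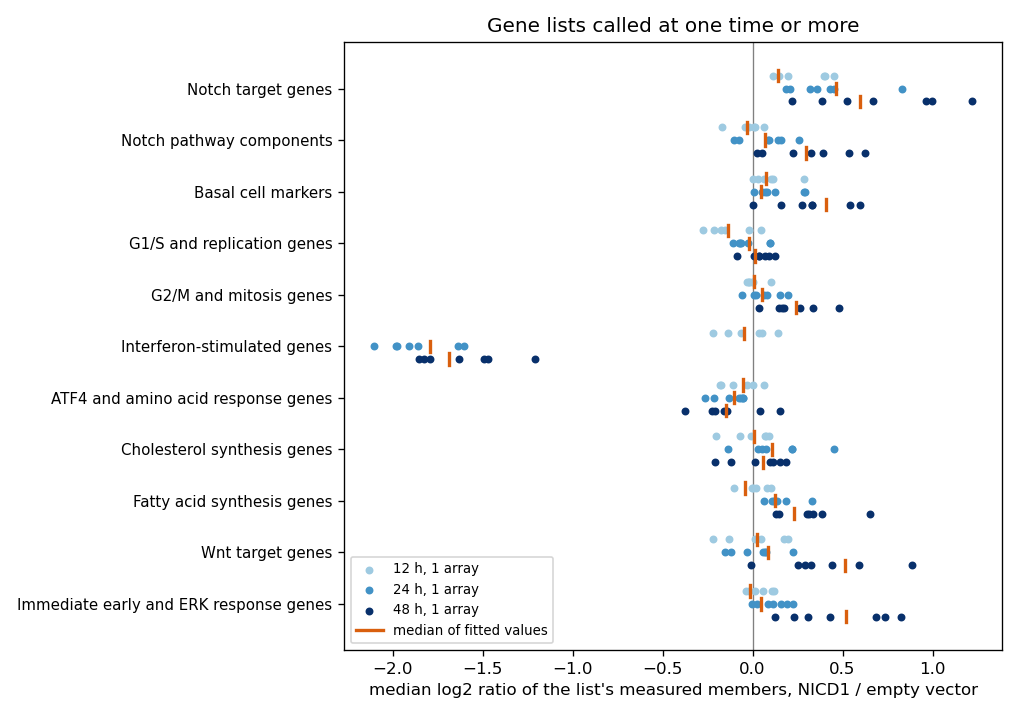
Median log2 ratio of NICD1 over empty vector (horizontal axis) of the measured members of each gene list that passed camera at 1 or more of the 3 times, with 1 point per array in a shade for 12, 24 or 48 h and an orange bar for the median of the fitted values, without error bars. Interferon-stimulated genes lie at -1.79 and -1.68 at 24 and 48 h, and Notch target genes at 0.14, 0.47 and 0.60 at the 3 times.

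Surfactant and alveolar type II genes, which define the cell type that MLE12 models, were not shifted at any time (adjusted p = 0.834, 0.825 and 0.173 at 12, 24 and 48 h). Of 15 measured, 1 fell at 12 h, Lyz2, none passed at 24 h, and 5 rose at 48 h; adjusted over the list alone the 48 h count was 5 higher and 1 lower. The surfactant protein gene Sftpc stood at -0.16 ± 0.22, 0.11 ± 0.20 and -0.38 ± 0.20 at the 3 times and Sftpb at 0.22 ± 0.17, -0.01 ± 0.15 and 0.29 ± 0.15, and none of these values passed. Ctsh, a cathepsin gene that acts on surfactant protein precursors, did not pass at any time (-0.32 ± 0.14 at 48 h). At 48 h the lipid transporter gene Abca3 was higher at 0.43 ± 0.11, with 1 array at -0.13 and the others between 0.29 and 0.57, Foxa1 at 0.39 ± 0.07, Etv5 at 0.31 ± 0.09 and Nkx2-1, the lung lineage transcription factor gene, at 0.32 ± 0.12 (adjusted p = 0.0455). None of these 4 passed without replicates 5, 6 and 7 or when fitted alone, although the list's shift then passed without those arrays (adjusted p = 0.0344), with a median of 0.19 and no member past the test. Sftpa1, Sftpd and Napsa were not analysed here.

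Apart from basal cell markers, the lists of other epithelial states and cell types did not pass camera at any time; without 48 h replicates 5, 6 and 7, epithelial junction and keratin genes passed at 24 h (adjusted p = 0.0415 against 0.0685). At 48 h, 3 of 14 alveolar type I markers were higher, among them Cav1 (0.52 ± 0.09), and 2 lower. Of 10 club and goblet cell markers 1 was higher, the secretoglobin gene Scgb1a1 (0.93 ± 0.23), and 1 lower. Of 9 ciliated cell markers 1 was lower, and of 8 neuroendocrine markers 1 was higher. Of 17 epithelial junction and keratin genes 4 were higher. Of 13 mesenchymal transition genes 2 were higher, the fibronectin gene Fn1 (0.75 ± 0.16) and Snai1 (0.77 ± 0.16), a repressor of epithelial genes, and both passed without replicates 5, 6 and 7. Of 10 TGF-beta target genes 3 were higher, and of 10 fibroblast markers 1, Col1a1 (1.10 ± 0.15). Of 7 leukocyte markers 1 was lower. None of 8 endothelial markers passed. Of these named genes only Col1a1 passed fitted alone (adjusted p = 0.0256), and Cav1 did not pass without replicates 5, 6 and 7 (0.0519). Adjusted over the list alone, the ciliated and neuroendocrine lists had no member past the test and the other counts were the same. In the fit without replicates 5, 6 and 7, members that passed were 1 club and goblet gene, 2 mesenchymal transition genes and 1 fibroblast gene, all higher, and 1 epithelial junction gene higher and 1 lower. No member of the alveolar type I, ciliated, neuroendocrine, TGF-beta, leukocyte or endothelial lists passed in that fit, and fitted alone only the fibroblast gene did.

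The remaining lists did not pass camera at 48 h either. Of 16 NF-kB and inflammatory genes 5 were higher, among them Nfkbia (0.46 ± 0.10), the NF-kB inhibitor gene, and the chemokine gene Ccl20 (0.61 ± 0.11), and 1, Il6, was lower (list adjusted p = 0.127). Of 17 ATF4 and amino acid response genes 6 were lower and 3 higher (list adjusted p = 0.167): Ddit3 (-0.99 ± 0.10), which encodes the stress factor CHOP, Atf4 itself (-0.71 ± 0.11), Trib3 (-0.56 ± 0.09) and the serine synthesis gene Phgdh (-0.54 ± 0.09) fell. Without replicates 5, 6 and 7 that list was shifted down (adjusted p = 0.000103, 5 lower and none higher), and these 4 passed; fitted alone, only Ddit3 of the 4 passed (adjusted p = 0.00772). Of 14 p53 target genes 4 were higher, among them Perp (0.51 ± 0.09), and 1 lower. Of 15 ER chaperone genes 3 were higher and 3 lower. Of 18 hypoxia and glycolysis genes 6 were higher and 1 lower, of 10 NRF2 target genes 3 and 2, of 19 lysosome genes 1 and 6, and of 16 ribosome biogenesis genes 4 and 2. Of 9 heat shock genes 4 were higher and 1 lower, and of 7 epithelial ion transport genes 1 and 0. Adjusted over the list alone, counts differed for p53 targets (6 higher, 1 lower), NF-kB genes (6 and 1), ATF4 genes (4 and 7), lysosome genes (2 and 6) and ribosome biogenesis genes (4 and 3). Nfkbia (adjusted p = 0.0891) did not pass without replicates 5, 6 and 7, and Nfkbia, Ccl20 and Perp did not pass fitted alone. In the fit without those arrays, 2 p53 targets were higher and 1 lower, 2 NF-kB genes higher and 1 lower, 1 hypoxia gene higher, and 1 gene each of the NRF2, lysosome and heat shock lists lower. No ER chaperone, ribosome biogenesis or ion transport gene passed in it, and fitted alone 1 NF-kB gene, 1 ATF4 gene and 1 lysosome gene passed, all lower. The list tests of NRF2 target genes moved from an adjusted p of 0.905 to 0.0163, shifted down with a median of -0.20, without replicates 5, 6 and 7.

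Over the 20 lists that passed at no time, the adjusted p lay between 0.353 and 0.935 at 12 h, 0.0633 and 0.969 at 24 h, and 0.127 and 0.927 at 48 h. Of their genes at 12 h, Lyz2 and Adm passed, and at 24 h Perp, Nfkbia (0.45 ± 0.10; adjusted p = 0.137 fitted alone) and Il6. In lists that passed, the median, the mean and the test had the same sign. At 48 h they differed in sign for fibroblast, endothelial and ribosome biogenesis genes, at 24 h for surfactant, mesenchymal transition, NRF2, ribosome biogenesis and ion transport genes, and at 12 h for Notch pathway, surfactant, cholesterol, hypoxia, Wnt and immediate early genes. With an estimated correlation, the calls that held were Notch target genes at all 3 times and interferon-stimulated genes at 24 and 48 h and in the differences of both from 12 h. Since Notch targets had set the direction of the columns, the sign of their shift was not tested independently.

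Between 12 and 24 h, the log2 ratios of interferon-stimulated genes dropped and that of Cdh15 rose further. The list's median difference was -1.89, and 23 of its 24 members passed with a lower log2 ratio at 24 h, all 24 adjusted over the list alone (camera adjusted p = 9.35e-110; adjusted p = 6.90e-09 with an estimated correlation). The differences were -3.24 for Iigp1 (adjusted p = 1.65e-06), -3.22 for Mx2 (4.43e-08), -3.14 for Ifit3b (0.000461), -2.93 for Trim30a (2.23e-09) and -2.67 for Gbp3 (3.71e-08), none of which had passed at 12 h. The log2 ratio of Cdh15 was higher at 24 h by 1.68 (adjusted p = 0.000303), and those of Sbk1 by 1.20 and Nr1h4 by 1.13, as their 12 h falls became smaller. Olfr1184 (1.57, adjusted p = 0.0185) and Aldh1b1 (1.15, adjusted p = 0.0399) passed too, though Aldh1b1 passed in 9 and Olfr1184 in 16 of the 20 fits that left out 1 array.

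In all, 153 genes differed between 12 and 24 h, 22 with a higher log2 ratio at 24 h and 131 with a lower one. Fatty acid synthesis genes had a median difference of 0.13 (adjusted p = 0.0125; adjusted p = 0.209 with an estimated correlation), with no member past the test. The difference for Notch target genes was not a pass (adjusted p = 0.131). Of 9 genes higher at 12 h, 7 were higher at 24 h, against 0.0333 for independent lists (Fisher's exact test, one-sided, p = 2.38e-16), and of 39 lower, 13 were lower at 24 h, against 0.505 (p = 1.23e-15). Both lists came from the same fit, with a shared variance per gene and a shared dye term. They were thus not independent, and the Fisher p-values describe the overlap without testing it.

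Between 24 and 48 h, 350 genes differed, 182 with a higher and 168 with a lower log2 ratio at 48 h. Leaving out 1 array in turn gave between 9 and 2103 genes, and a fit with a replicate block gave 10. Akr1c14, of the aldo-keto reductase family, went from 0.67 ± 0.11 to -0.69 ± 0.11 (difference -1.35, adjusted p = 0.000625). The log2 ratio of Adam8, a metalloprotease gene, rose by 1.48 (adjusted p = 0.00296) to 1.03 ± 0.15, and the fall of Oasl2 became smaller by 1.36 (adjusted p = 0.00359). Without 48 h replicates 5, 6 and 7, 8 genes differed between these times, 7 of them shared; Adam8 (adjusted p = 0.00844) and Akr1c14 (0.0205) passed and Oasl2 (0.096) did not. For their values at 48 h, Adam8 (adjusted p = 0.0642) and Akr1c14 (0.0764) did not pass fitted alone, and Akr1c14 did not pass without replicates 5, 6 and 7 (0.0619).

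Several further differences between 24 and 48 h passed narrowly, among them Glod5 (1.64), Ankrd11 (1.35), which encodes a chromatin regulator, Mslnl (1.35, with 1 array at 3.63 at 48 h and the others between 0.35 and 1.62), Olfr1216 (-1.73), Prl7a1 (-1.64), a prolactin family gene with 1 array at 2.68 at 24 h and the others between -0.18 and 0.58, and Ifi27l2a (-1.42), with adjusted p between 0.0375 and 0.0492. None of these passed without replicates 5, 6 and 7 (adjusted p between 0.283 and 0.423), and each passed in 3 to 9 of the 20 fits that left out 1 array. Notch pathway components had a median difference of 0.32 (adjusted p = 0.0363; adjusted p = 0.562 with an estimated correlation) and 1 member past the test. Their adjusted p was 0.182 without replicates 5, 6 and 7, and 0.0778 with array weights. Of 63 genes higher at 24 h, 48 were higher at 48 h, against 8.84 for independent lists (Fisher's exact test, one-sided, p = 1.05e-28), and of 221 lower, 174, against 30.5 (p = 4.09e-107). Both lists again came from the same fit and were not independent, so these p-values describe the overlap without testing it.

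Between 12 and 48 h, 1563 genes differed, 727 with a higher and 836 with a lower log2 ratio at 48 h; without 48 h replicates 5, 6 and 7 there were 283, of which 245 were shared. Leaving out 1 array in turn gave between 593 and 2695. Interferon-stimulated genes had a median difference of -1.73 with 22 of 24 passed as lower, and all 24 adjusted over the list alone (adjusted p = 2.44e-34; adjusted p = 6.17e-05 with an estimated correlation), led by Ifit3b (-3.58), Trim30a (-3.25), Ifi27l2a (-2.94), Iigp1 (-2.91) and Mx2 (-2.77). The log2 ratio of Sbk1, lower at 12 h, was higher by 2.40 at 48 h than at 12 h (adjusted p = 3.48e-07). Those of Hey1 (2.21, adjusted p = 2.35e-05), Col6a1 (2.36, 0.00314) and Glod5 (2.31, 0.00102) were higher at 48 h too. The log2 ratio of the collagen prolyl hydroxylase gene P4ha3 was higher by 2.43 (adjusted p = 0.0193), with 1 array at -2.91 at 12 h and the others between -0.95 and -0.22. The P4ha3 difference did not pass without replicates 5, 6 and 7 (adjusted p = 0.0887).

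Lists with a shift between 12 and 48 h were also fatty acid synthesis genes (median difference 0.31, 5 members higher; adjusted p = 0.178 with an estimated correlation), immediate early and ERK response genes (0.49, 5 members; adjusted p = 0.277 with an estimated correlation), G2/M and mitosis genes (0.20, 5 members; adjusted p = 0.277 with an estimated correlation), Notch pathway components (0.33, 2 members; adjusted p = 0.277 with an estimated correlation) and Wnt target genes (0.42, 1 member; adjusted p = 0.263 with an estimated correlation). Their adjusted p with the preset correlation lay between 0.00125 and 0.0467. Without replicates 5, 6 and 7, Notch pathway (0.122) and Wnt target genes (0.27) did not pass. Of 39 genes lower at 12 h, 6 were lower at 48 h, against 5.39 for independent lists (Fisher's exact test, one-sided, p = 0.456), and of 9 higher, 5 were higher, against 1.26 (p = 0.00416). These lists shared a fit as well and were not independent.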

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

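In this part, the tests of the other rows of genes lower at 12 h, of a batch at 48 h, of dye and plasmid for the interferon-stimulated genes, of the deposited signs among the assignments and of assignments that keep 48 h replicates 5, 6 and 7 together, and the fit without 48 h replicates 5, 6 and 7 were chosen only after the results were seen.

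Interferon-stimulated genes such as Mx2 and Ifit3 did not pass at 12 h and were lower at 24 and 48 h, and their differences between times passed: a median of -1.89 from 12 to 24 h and -1.73 from 12 to 48 h. A dye effect is argued against, because the list's median was at most -1.21 on each of the 14 arrays at 24 and 48 h, of which 6 carried the NICD1 RNA in Cy5 and 8 in Cy3. Other RNA binding to single probes is argued against narrowly, since 76.2% of the rows of members with several rows were lower at 24 h (16 of 21; 95% interval 52.8 to 91.8). The bound for that test was tightened after its value was seen. A difference between the 2 transfections in plasmid amount or in the response to plasmid cannot be told apart from an effect of NICD1, because construct and plasmid differed together on all 20 arrays. Of the 64 ways to turn the signs of the 24 h arrays, 1, the one used, gave as many genes (284, highest other 22). That share is under 0.05 and is the lowest that 64 ways can give. No 24 h array was turned, though their signs too had been checked after the data were seen. Chance is therefore argued against for that count but not excluded.

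Most genes that passed at 12 h were lower: the 39 had medians of -1.20, -0.37 and -0.15 at 12, 24 and 48 h, and since they were chosen at 12 h, later values nearer 0 follow in part from that choice. Of the 39, 5 had several rows. In the fit per row, 11 genes with several rows, among them Vpreb3 and Sost, had 1 row lower at 12 h. The 14 other rows of those 11 genes had a median of 0.046, and 0% of them were lower. This argues against a fall of the transcripts of those 11 genes only as far as the other rows had signal over background, which was not assessed. A candidate explanation is RNA other than the gene's own binding to single probes. For the 34 genes with 1 row, among them Hspb9, Gna15 and Sbk1, a fall cannot be told apart from such binding, because no other row can check it. Of the 32 ways to turn the signs of the 12 h arrays, 1, the one used, gave as many genes (48, highest other 0). The sign of 12 h replicate 3 was chosen after its values were seen, and its deposited sign gave 0 genes, so these assignments do not settle whether chance gave the 48.

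The 48 h replicates 5, 6 and 7 stood apart, with a lowest correlation of 0.653 among them against a highest of 0.322 among replicates 1 to 4, though replicate 4 came closer to them, at 0.368, 0.399 and 0.341, and its Mrpl median (-0.45) lay between theirs (-0.79 to -0.67) and those of replicates 1 to 3 (-0.20 to -0.05). With a trend with gene length taken off, 4517 of the 4747 genes at 48 h still passed, which argues against it as the whole cause of that count. The length was the gene's span, which correlated with the log2 ratio at only 0.163 to 0.168 on these arrays. Transcript length was not tested. With the arrays scaled 2910 passed, which argues against a wider spread on these arrays as the whole cause of the count, though not of part of it. Neither fit tests why these 3 arrays correlate with each other. Scaling leaves a correlation unchanged, and correlations were not taken again without the trend. A preparation or hybridisation batch stays open, since the labels give none, and so does a stronger response in these replicates, which no test here separates from it. Of the 64 ways to turn the signs of the 48 h arrays, 1, the one used, gave as many genes (4747). The highest other gave 4587, with the ratio of 48 h replicate 3 as deposited and its dye exchanged, and only 16 of the 64 keep replicates 5, 6 and 7 under 1 sign, too few for a share under 0.05.

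Counts of genes that differed between times were 153 from 12 to 24 h, 350 from 24 to 48 h and 1563 from 12 to 48 h. Of 100 assignments of the arrays to the times, the real one included, 1 gave at least 153 (highest other 82), 2 at least 350 (highest other 874) and 4 at least 1563 (highest other 2763). With the 2 turned arrays as deposited, the real assignment gave 46, 2 and 306 genes, and 1, 1 and 5 of the 100 gave as many (highest others 1, 1 and 2251). With 48 h replicates 5, 6 and 7 kept on 1 side, 2 of 100 gave at least 350 (highest other 815) and 6 at least 1563 (highest other 2825). For 12 against 24 h chance is argued against, with the signs used and as deposited, but not excluded, since 1 of 100 is the lowest share possible here. Chance is left open for 12 against 48 h. For 24 against 48 h the shares are under 0.05, but the count is not stable: it was 2 with the deposited signs, 8 without 48 h replicates 5, 6 and 7, and between 9 and 2103 with 1 array left out. Assignments with more genes than the real one point to a structure of the samples. In the assignment with 874 genes, 24 h replicate 3 and 48 h replicate 2 had changed places, and in that with 2763 genes 48 h replicate 2 stood with the 12 h arrays.

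Between 12 and 24 h the log2 ratio was higher at 24 h in Cdh15 (1.68), Olfr1184 (1.57), Sbk1 (1.20), Aldh1b1 (1.15) and Nr1h4 (1.13), and lower in Iigp1 (-3.24), Mx2 (-3.22), Ifit3b (-3.14), Trim30a (-2.93) and Gbp3 (-2.67). Between 24 and 48 h it was higher at 48 h in Glod5 (1.64), Adam8 (1.48), Oasl2 (1.36), Ankrd11 (1.35) and Mslnl (1.35), and lower in, among others, Olfr1216 (-1.73), Prl7a1 (-1.64), Ifi27l2a (-1.42) and Akr1c14 (-1.35). Between 12 and 48 h it was higher at 48 h in P4ha3 (2.43), Sbk1 (2.40), Col6a1 (2.36), Glod5 (2.31) and Hey1 (2.21), and lower in Ifit3b (-3.58), Trim30a (-3.25), Ifi27l2a (-2.94), Iigp1 (-2.91) and Mx2 (-2.77). The other lists that differed were fatty acid synthesis genes from 12 to 24 h (0.13), Notch pathway components from 24 to 48 h (0.32), and, from 12 to 48 h, Notch pathway components (0.33), G2/M and mitosis genes (0.20), fatty acid synthesis genes (0.31), Wnt target genes (0.42) and immediate early and ERK response genes (0.49). Each of these differences passed a test of the difference itself, but none of these other lists held with an estimated correlation (adjusted p between 0.178 and 0.562).

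A single array lay far from the others of its time in 26 of 378 groups of values tested, where chance gives about 1 in 20, or 18.9. Among Notch genes these were Hes1 at 48 h (1.01 on replicate 6, others -0.21 to 0.30) and the median of the Notch target list at 24 h (0.83 on replicate 4, others 0.18 to 0.45). Among interferon genes they were Ifnb1 at 12 h (-5.02 on replicate 1), Ifit3b at 24 h (-4.38 on replicate 3) and Gbp3 at 12 h (-0.59 on replicate 3, others 0.06 to 0.26). At 12 h they were also Lyz2 (-2.94 on replicate 2), Col6a1 (2.22 on replicate 4), P4ha3 (-2.91 on replicate 1) and Axin2 (-3.19 on replicate 6). At 24 h they were Abca3 (-0.78 on replicate 7), Glod5 (-0.56 on replicate 4), Nr1h4 (0.57 on replicate 3), Prl7a1 (2.68 on replicate 4), Foxm1 (0.23 on replicate 6) and Ccl20 (-0.33 on replicate 1). At 48 h they were Abca3 (-0.13 on replicate 3), Parp10 (1.54 on replicate 7, others -0.98 to -0.52), Sbk1 (-0.66 on replicate 7), Nts (5.23 on replicate 1), Col6a1 (4.67 on replicate 2) and Mslnl (3.63 on replicate 7). For list medians they were mesenchymal transition genes (-0.31), G2/M and mitosis genes (0.10), both on 12 h replicate 1, hypoxia and glycolysis genes (-0.15 on 12 h replicate 4), lysosome genes (-0.27 on 24 h replicate 3) and p53 target genes (0.41 on 48 h replicate 7).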

How the results depend on the processing

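The fits with the 2 turned arrays as deposited, without those 2 arrays, without 48 h replicates 5, 6 and 7, with every array labelled NICD1 in Cy3 turned, and with the gene length trend taken off were chosen only after the results were seen. Where a value below differs from the report, the cause was not tested unless stated.

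Counts at 12 h moved from 48 to 18 with each time fitted alone, where fewer arrays share the variance, and to 83 with array quality weights. At 24 h, 284 genes became 513 with arrays scaled to the same spread, 570 with weights, 432 rows in the fit per row and 125 with an absolute log2 ratio of at least 1. At 48 h, 4747 genes became 234 with each time fitted alone, 2910 with scaling, 1746 with weights, 630 without replicates 5, 6 and 7, 9070 rows in the fit per row, 2789 with an adjusted p under 0.01 and 263 with an absolute log2 ratio of at least 1. More rows than genes were tested in the fit per row. Of the genes that passed at 48 h in the report, 231 passed fitted alone and 567 without replicates 5, 6 and 7.

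Between 12 and 24 h, 153 became 232 with weights. Between 24 and 48 h, 350 became 128 without the dye term, 197 with scaling, 19 without the genes of lowest SD, 14 with weights, 222 with robust moderation, 14 rows in the fit per row, 1886 without the 2 turned arrays, 8 without 48 h replicates 5, 6 and 7, 8 with an adjusted p under 0.01 and 56 with an absolute log2 ratio of at least 1. Between 12 and 48 h, 1563 became 1021 without the genes of lowest SD, 750 with weights, 283 without 48 h replicates 5, 6 and 7, 307 with an adjusted p under 0.01 and 289 with an absolute log2 ratio of at least 1. With the replicate number as a block, although the arrays showed no pairing by number, 10 genes differed between 24 and 48 h and 555 between 12 and 48 h.

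With the 2 arrays as deposited, 0 genes passed at 12 h and 181 at 24 h, and 46, 2 and 306 differed between 12 and 24, 24 and 48, and 12 and 48 h; no list, 0 of 31, was shifted at 12 h. With every array labelled NICD1 in Cy3 turned, 1, 2 and 0 genes passed at 12, 24 and 48 h and 0, 0 and 0 differed between times.

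Lists shifted at 12 h were 2 in the report and 1 without the genes of lowest SD, 1 without the 2 turned arrays and 1 with an estimated correlation. At 24 h, 6 became 3 without the genes of lowest SD, 2 with an estimated correlation and 3 with fry. At 48 h, 8 became 2 with an estimated correlation and 18 with fry. The lists were not run in the fit per row.

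Without 48 h replicates 5, 6 and 7, 4 values at 48 h that passed in the report or in that fit reversed in sign. They were NRF2 target genes (-0.20, by the sign of the list test), Emp2 (-0.051), Txnrd1 (-0.040) and Hsph1 (-0.017). Values that passed in neither fit, such as Lyz2, could change sign too and were not counted. Of 504 values of named genes at a time, 60 then lost and 8 gained a pass; with each time fitted alone 104 lost it, and with weights 38 lost and 15 gained it. Of the 30 named gene differences, 8 lost their pass without those 3 arrays and 23 with the 2 arrays as deposited.

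With each array left out in turn, 35 to 54 genes passed at 12 h, 246 to 302 at 24 h and 2992 (without 48 h replicate 6) to 5343 (without 48 h replicate 3) at 48 h. Between 12 and 24 h, 125 to 165 differed. Between 24 and 48 h the count ran from 9 to 2103, and each of the 20 arrays moved it by more than 1.5 times. Without 12 h replicates 1 to 6 it was 73, 80, 60, 67, 29 and 63, without 24 h replicates 1 to 7 it was 17, 11, 80, 11, 10, 25 and 9, and without 48 h replicates 1 to 7 it was 1529, 1785, 2103, 12, 9, 9 and 13. Between 12 and 48 h the count ran from 593 to 2695: it was 808, 1011, 911, 811 and 1008 without 12 h replicates 1, 3, 4, 5 and 6, and 2548, 2695, 901, 783, 593 and 979 without 48 h replicates 2 to 7. Lists shifted were 1 (without 12 h replicate 3) to 2 at 12 h, 4 (without 24 h replicate 4) to 9 (without 24 h replicate 3) at 24 h and 7 to 9 at 48 h.

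Centring each array on its median and taking off the gene length trend left every count of genes and lists within 1.5 times that of the report. Single channel intensities were not analysed here, so what signal over background limits was not assessed.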

Other observations

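All tests of gene families in this part were chosen only after the results were seen, as 273 groups of genes that share a symbol stem, of which 1, 12 and 23 passed camera at 12, 24 and 48 h. Families were tested with the preset correlation of 0.01 only, and not with an estimated correlation. For the fixed lists at 48 h that stricter test left 2 of 8 calls. Several members of the Oas and Parp symbol families were lower, and Oas shares Oas1a and Oas2 with the fixed list of interferon-stimulated genes. The single genes named in this part were picked after the results were seen. Of 9 oligoadenylate synthetase genes (Oas), 8 were lower at 24 h, with a median of -1.24, and 8 at 48 h, with a median of -1.50; Oas1f stood at -2.10 ± 0.10 and Oas3 at -1.24 ± 0.11 at 24 h. Of 12 Parp genes 5 were lower at 24 h, among them Parp14 (-1.68 ± 0.11) and Parp12 (-1.63 ± 0.14), although Parp10 had been higher at 12 h. With each time fitted alone, Parp10 did not pass at 12 h (adjusted p = 0.0651) and was itself lower at 24 h (-0.82, adjusted p = 0.0366). Tlr3, a receptor for double-stranded RNA, stood at -1.55 ± 0.14 at 24 h. The inducible proteasome subunit genes Psmb8, Psmb9 and Psmb10 were lower at 24 h (-0.84 ± 0.10, -1.18 ± 0.15 and -0.84 ± 0.11).

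At 48 h, in the fit with replicates 5, 6 and 7 included, mitochondrial ribosome genes were lower: 35 of 49 Mrpl genes, with a median of -0.43 (adjusted p = 3.85e-10), among them Mrpl1 (-0.94 ± 0.12), and 17 of 29 Mrps genes, with a median of -0.42, among them Mrps10 (-0.58 ± 0.09). Of 11 Psmb genes 9 were lower, and of 18 Serpinb genes 10, among them Serpinb9d (-1.50 ± 0.17). Of 38 collagen genes 13 were higher (median 0.19, adjusted p = 0.0035), among them Col5a3 (1.84 ± 0.13, n = 6), Col6a2 (1.18 ± 0.10) and Col18a1 (1.10 ± 0.09), and of 32 kinesin genes 15 (median 0.27), among them Kif18b (0.48 ± 0.09). Without replicates 5, 6 and 7, 5 Mrpl, 2 Mrps and 3 Psmb genes were lower and 6 collagen and 1 kinesin gene higher, and these 5 families passed camera, whereas Serpinb did not (adjusted p = 0.0539). The medians of these 5 then were -0.18, -0.21, -0.26, 0.08 and 0.19, in that order. Families were not tested with 48 h fitted alone. Calls of the single genes named here in either fit are not given. The Mrpl medians were -0.67, -0.79 and -0.79 on replicates 5, 6 and 7, -0.45 on replicate 4 and between -0.20 and -0.05 on replicates 1 to 3. The size of that fall thus rested mostly on replicates 4 to 7.

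Rows without a gene name were fitted singly: of 8541 at 12 h, 2 were higher and 12 lower. A dye effect passed for 784 genes. The Spearman correlation of the log2 ratio with gene span was between 0.163 and 0.168 on 48 h replicates 5, 6 and 7, and their array weights were 0.417, 0.447 and 0.251.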
